A study of Strongylocentrotus purpuratus with 165 samples.

How the data were processed

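The series holds 165 single embryos of the purple sea urchin Strongylocentrotus purpuratus. Per the labels' protocols, total RNA of each embryo was extracted with Trizol and polyadenylated RNA was amplified with CEL-Seq, a barcoded method based on in vitro transcription that reads the 3′ ends of transcripts, and the library was treated with a duplex-specific nuclease. Per the submitters' processing notes, CASAVA 1.8, Bowtie2 2.1.0 and HTSeq 0.5.4p3 were used to make the table; the genome build and gene models are not given in the sources used here, nor is the use of molecular identifiers. The deposited values are raw counts per gene model, not normalized by the authors. The growth text in the labels describes another animal, so rearing conditions are not reported here. Each label gives a time as a number with no unit; it is called labelled time throughout.

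The deposited table has 21092 gene models, of which 8 carry an older type of ID, 92 spike-in RNAs and 5 HTSeq summary lines. Of these lines 3 are 0 in every library. Counts not aligned made up a median of 55.5% of a library, counts outside gene models 10.7%, spike-ins 6.68% and gene models 26.8%. Summary lines and spike-ins stayed out of library sizes and of the tests of gene models. Spike-ins entered only the relation of gene counts per spike-in count with labelled time. Gene model counts per library ran from 26077 to 2451801, with a median of 467079. Reads amplified in vitro and not known to be collapsed to molecules are not independent molecules, so a count gives less precision than its size. None of the IDs (0 of 21092) matched the 33503 entries of a gene table of another assembly (Spur_5.0), and the files do not pair the IDs with names. The 21 gene lists fixed beforehand could not be matched or tested, and gene models are given by ID only.

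Embryos were grouped by labelled time into 7 windows fixed from the labels: -20 to 320, 360 to 720, 760 to 1440, 1480 to 2160, 2200 to 2880, 2920 to 3600 and 3640 to 4560. The embryos of a window stand at different times and are not stated to come from separate cultures or parents. The p-values therefore measure the spread between these embryos only. The embryo numbers in the titles were divided into 4 runs: run A (1 to 51), run B (52 to 101), run C (102 to 135) and run D (136 to 165). Labelled time starts over at embryos 52 and 136. At embryo 102 it goes on from 3680 to 3800, and within run C it goes back at embryos 117, 118, 126 and 128, so run C need not be 1 series. The labels do not call these runs batches.

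Libraries with fewer gene counts than 10% of the median were left out, which removed embryo 14 (labelled time 880, 39530 counts) and embryo 148 (labelled time 1520, 26077 counts). The other 163 libraries were fitted together in edgeR 4.0.16 (R 4.3.3) with TMM factors, filterByExpr by window (minimum count 10) and the quasi-likelihood F-test, with no covariate. The filter left 11022 gene models, and p-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. All 7 windows were compared in 1 test, and each pair of neighbouring windows in a further test (6 steps). The standard error of a log2 fold change is its size divided by the square root of F. CPM values use TMM-scaled library sizes summed over the tested gene models, except for the gene group and the single-embryo peaks under other observations, which use unscaled gene counts. The rule for naming gene models, fixed before the data were examined, took for each step the 2 largest rises and the 2 largest falls past the threshold with a mean of at least 20 CPM in the higher window. Because most of these rested on 1 embryo, a further rule was set, and then tightened, after the values were seen. It required that the call hold with the highest embryo of each window set to the CPM of the second highest, that the window medians (plus 1 CPM) differ at least 2-fold the same way, and that 1 embryo hold under 50% of the summed CPM of the higher window.

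The fit was tested on simulated data with the real means, dispersions and library sizes. Of gene models changed 2-fold in window 2 over window 1, 8% were recovered, and 12%, 29%, 26%, 41% and 49% in the 5 later steps, with 200 of 11022 gene models changed in each, some 2-fold and as many 4-fold. For 4-fold changes these shares were 60%, 81%, 96%, 94%, 94% and 97%. False calls were 1.46% to 4.23% of calls. The simulation drew each count independently around 1 mean per gene model and held no number runs, so real shares can be higher. Splits of the real embryos that ignored the windows, given under other observations, called medians of 92 to 248 gene models per step. The lowest of 13203 values of chi-square per degree of freedom between libraries was 4.45 (embryos 105 and 113), and the median was 22.4. The statistic takes counts as independent and so covers counting error only. It cannot exclude that 2 libraries came from the same embryo, and no library was left out by it.

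Breadth and similarity of expression were measured after thinning each library to 179497 gene counts, the 10th percentile, which left 146 libraries. The first principal component was taken from centred log2 CPM (prior count 2). Relations with labelled time were tested with 2-sided permutation tests (100000 resamples, Python 3.11.15, numpy 2.4.6), also within each number run. Alternatives fixed before the data were examined were DESeq2 size factors, library totals alone, no low-count filter, the DESeq2 1.42.0 test, number run as a covariate, run D alone or left out, other depth limits, no library at the negative time, window bounds moved 120 later, and a spline of time. Further ones, chosen after seeing the data, were the capped highest embryo, the robust form of the edgeR test, leaving out 4 libraries rich in 1 gene group, runs split at every backward step of labelled time as a covariate, and DESeq2 fold changes of named IDs. Scaling to the spike-ins was not used here.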

Results

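The time course covered 165 single sea urchin embryos at 116 labelled times between -20 and 4560, mostly 40 apart. Of these times 72 held 1 embryo, 39 held 2 and 5 held 3. The design implies a comparison of successive stages, and the embryos fell into 7 windows of labelled time with 13, 13, 23, 23, 22, 22 and 49 embryos. Median gene counts per library rose from 282153 in window 1 to 532072 in window 6 and were 500403 in window 7. Run A, run B and run D contributed to most windows, whereas run C lay entirely at labelled times 3800 to 4560. The labels name no treatment, and the comparisons are between times only.

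Along the first principal component the embryos moved most between labelled times 840 and 960. The component held 14.1% of the variance. The 29 embryos up to labelled time 840 lay between -107.0 and -55.1 on it, and the 17 embryos at 960 to 1440 between -35.3 and 14.8. Over all 163 embryos the component rose with labelled time (Pearson's r = 0.79, Spearman's rho = 0.76, permutation p = 1e-05 for each, the smallest the resamples can give, adjusted p = 1.22e-05 over 11 relations, r = 0.78 without the 2 embryos farthest from the median time). Within times up to 840 no relation was detected (r = -0.02, rho = 0.06, permutation p = 0.924 and 0.768). From 880 onwards r was 0.54 and rho 0.58 (permutation p = 1e-05 for each). Within runs A, B and D rho was 0.80, 0.84 and 0.78, and within run C, which spans late times alone, rho was 0.36 and r -0.11 (permutation p = 0.0394 and 0.583). The negative r rested on embryo 135, at -48.4 beside 10.5 or more in the others of run C, and without it r was 0.32 and rho 0.48.

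**Figure D1:**
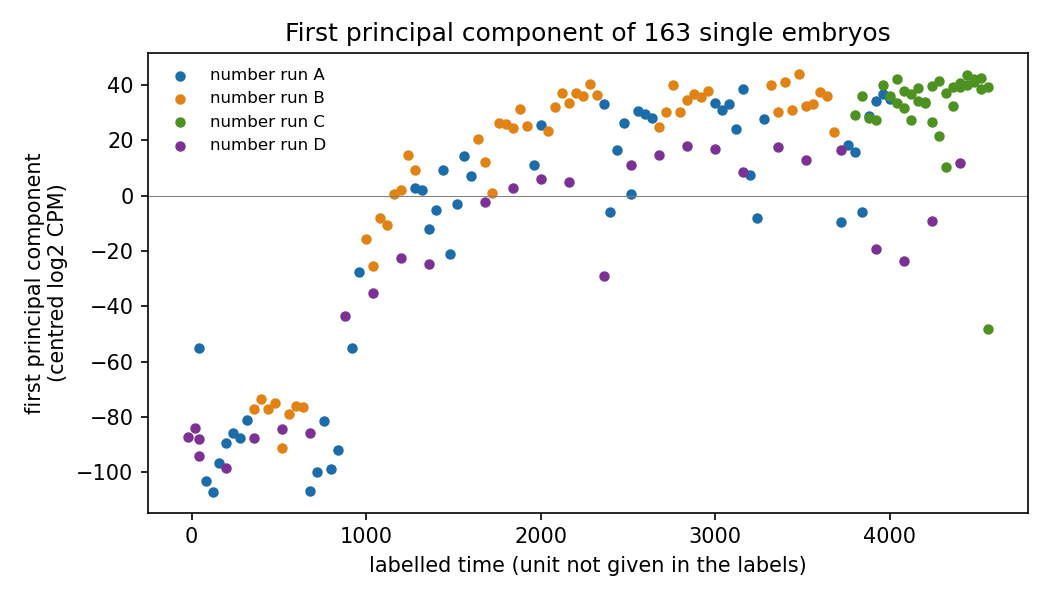
First principal component of centred log2 CPM (y axis) against labelled time (x axis, unit not given), 1 point per embryo, coloured by number run. Embryos up to labelled time 840 sit between -107.0 and -55.1, and those at 960 to 1440 between -35.3 and 14.8.

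Across the 7 windows, 7025 of 11022 gene models changed (edgeR quasi-likelihood F-test, adjusted p under the threshold). Of these, 1770 had their highest mean log2 CPM in window 1, 849 in window 2, 902 in window 3, 828 in window 4, 594 in window 5, 1039 in window 6 and 1043 in window 7. The lowest mean fell in window 1 for 1889 of the changed gene models and in window 2 for 1459, against 571 in window 6. Run D alone, with 29 libraries, gave 3695 changed gene models. Scaling by library totals alone moved the count of gene models highest in window 2 to 2278.

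Embryos of the same labelled time were less alike across runs than embryos of nearby times within a run. After thinning, the median Spearman's rho across tested gene models was 0.61 over 40 pairs of same-time embryos, ranging from 0.46 to 0.70. The 12 such pairs within a run had a median of 0.66 and the 28 across runs 0.58. Most of the pairs across runs included an embryo of run D, and most of those within a run were late embryos of run C. The contrast is therefore mixed with which runs were paired. Pairs 160 apart within a run had a median of 0.67, and those over 2000 apart within a run 0.50. These values are across gene models, which are not independent replicates, and no test was made on them.

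The number of gene models with a count at the thinned depth averaged 12186 ± 1063 (SD, n = 12) in window 1 and 14176 ± 688 (SD, n = 10) in window 2. The embryos of window 1 counted here were of runs A and D and those of window 2 of runs B and D, so this difference is mixed with number run. It was 12198 ± 926 (SD, n = 19) in window 4 and 13102 ± 1257 (SD, n = 44) in window 7. It had no relation to labelled time that passed the test over 146 embryos (r = 0.11, rho = 0.13, permutation p = 0.206 and 0.124, adjusted p = 0.394 and 0.270 over 8 relations, r = 0.09 without the 2 farthest). Within runs A, B and C r was 0.01, -0.26 and -0.18, none of which passed (permutation p = 0.963, 0.0817 and 0.343). In run D r was 0.43 (permutation p = 0.0245, adjusted p = 0.196, n = 27).

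Between neighbouring windows the calls numbered 131, 2453, 1412, 397, 354 and 585 in order of time. The rule fixed beforehand took 4 IDs per step, 24 in all, and in 18 of these over 88% of the summed CPM of the higher window came from 1 embryo. The 5 rule-picked IDs with under 40% in 1 embryo are named for their steps. The other IDs named there were chosen after their values were seen, by the requirement that the call hold with the highest embryo capped, that the window medians also move and that no embryo hold 50% of the CPM. Capping aside, these and the 5 rule-picked IDs kept their sign in the 4 or 5 alternatives run on each, and a call lost in an alternative other than run D alone is given at its step.

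**Figure D2:**
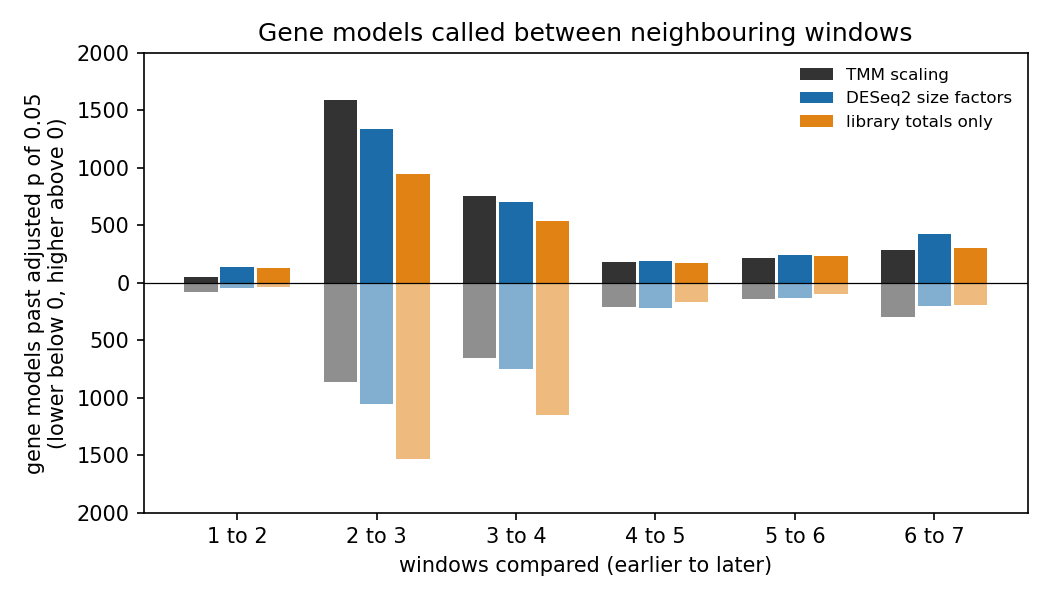
Gene models past the adjusted p of 0.05 in each step between neighbouring windows (x axis), higher in the later window above 0 and lower below 0 (y axis, number of gene models), under 3 scalings. Step 2 to 3 has the most calls, 1587 higher and 866 lower with TMM, and the split between higher and lower moves with the scaling.

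From window 1 to window 2 few gene models passed the test, which recovered 8% of simulated 2-fold changes there. WHL22.286275.0 fell from a median of 232 to 89.1 CPM (mean 409 ± 343 SD against 102 ± 66.9 SD, n = 13 each), a log2 fold change of -2.03 ± 0.37 (SE, adjusted p = 1.40e-04), and 13 of 13 earlier embryos were above the later median. WHL22.184143.1 fell from a median of 12.4 to 2.45 CPM (log2 fold change -2.49 ± 0.66 SE, adjusted p = 0.0319), with 11 of 13 earlier embryos above the later median. WHL22.643884.0 rose from 3.00 to 15.9 CPM (2.32 ± 0.62 SE, adjusted p = 0.0319), with 12 of 13 later embryos above the earlier median. The calls on WHL22.184143.1 and WHL22.643884.0 were lost without run D (-2.75, adjusted p = 0.0599, and 1.72, adjusted p = 0.261). WHL22.237823.0 rose from 2.60 to 13.2 CPM (2.03 ± 0.55 SE, adjusted p = 0.0364), with 11 of 13 above. In all, 53 gene models were higher and 78 lower. Of these, 53 and 77 changed at least 2-fold. Among all 11022 gene models tested, 1557 had an unadjusted p under 0.05. The share of calls that were higher was 40.5% with TMM, 74.0% with DESeq2 size factors and 79.4% with library totals, as the median log2 fold change of all gene models moved from -0.14 to 0.08 and 0.14. Capping the highest embryo of each window gave 33 higher and 45 lower, of which 20 and 27 were among the 53 and 78, and 22 of 40 splits of these 26 embryos, the real one included, gave at least as many calls as the real windows. With number run as a covariate the step had 110 higher and 134 lower, and 4 of 40 splits within runs gave as many.

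From window 2 to window 3 the most gene models passed the test. WHL22.451280.0 rose from a median of 11.9 to 1289 CPM (mean 17.8 ± 18.8 SD, n = 13, against 1518 ± 1351 SD, n = 22), a log2 fold change of 6.25 ± 0.67 (SE, adjusted p = 3.03e-14), and 20 of 22 later embryos exceeded the earlier median. WHL22.335235.0, picked by the rule, was at a median of 0 CPM in window 2 (mean 0.347 ± 0.695 SD) and at 53.6 CPM in window 3, with 18 of 22 later embryos above the earlier median and a fitted log2 fold change of 6.29 ± 1.06 (SE, adjusted p = 6.63e-07). WHL22.161583.0, also picked by the rule, fell from a median of 20.5 to 0.51 CPM (-4.72 ± 0.60 SE, adjusted p = 3.98e-11). WHL22.584483.0 fell from 79.7 to 8.96 CPM (-3.97 ± 0.44 SE, adjusted p = 1.87e-13), with 11 of 13 earlier embryos above the later median. A total of 1587 gene models were higher in window 3, 1442 of them at least 2-fold, and 866 were lower, 736 of them at least 2-fold. The direction of the balance rested on the scaling: 64.7% of calls were higher with TMM, 55.9% with DESeq2 size factors and 38.3% with library totals. The median log2 fold change of all gene models was 0.12, 0.02 and -0.22 in the same order.

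From window 3 to window 4 rises and falls were nearly balanced under TMM. Window 3 spans the shift along the first principal component: embryos 11 to 13 (labelled times 760 to 840) lay at -98.6 to -81.6 and others reached 14.8. Steps 2 and 3 therefore both use a window that mixes embryos from before and after the shift. WHL22.208335.2, picked by the rule, fell from a median of 173 to 4.78 CPM (mean 243 ± 252 SD against 8.68 ± 11.5 SD, n = 22 each), a log2 fold change of -4.88 ± 0.51 (SE, adjusted p = 1.12e-13), and 20 of 22 earlier embryos were above the later median. WHL22.225867.0 fell from 51.5 to 12.4 CPM (-3.11 ± 0.57 SE, adjusted p = 1.38e-05). WHL22.239320.0 rose from 7.66 to 57.2 CPM (3.02 ± 0.40 SE, adjusted p = 2.55e-09), with 21 of 22 later embryos above the earlier median. WHL22.480550.0 rose from 4.66 to 42.5 CPM (2.93 ± 0.52 SE, adjusted p = 5.09e-06). There were 759 gene models higher and 653 lower, of which 608 and 509 changed at least 2-fold. Higher calls made up 53.8% with TMM, 48.5% with DESeq2 size factors and 32.0% with library totals, while the median of all gene models was -0.04, -0.09 and -0.26.

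Fewer gene models passed the test from window 4 to window 5. WHL22.699375.0 rose from a median of 19.8 to 355 CPM (mean 44.4 ± 57.9 SD against 425 ± 380 SD, n = 22 each), a log2 fold change of 3.22 ± 0.51 (SE, adjusted p = 3.33e-06), with 19 of 22 later embryos above the earlier median. WHL22.242989.0 rose from 6.79 to 132 CPM (3.14 ± 0.61 SE, adjusted p = 1.49e-04), with 18 of 22 above. WHL22.57355.0 fell from 24.9 to 0.82 CPM (-2.12 ± 0.57 SE, adjusted p = 0.0145), a call lost without run D (-1.70, adjusted p = 0.130). WHL22.166312.0 fell from 14.8 to 6.61 CPM (-2.14 ± 0.50 SE, adjusted p = 0.00293). A total of 184 gene models were higher and 213 lower, of which 168 and 195 changed at least 2-fold. All 4 IDs picked by the rule had over 91% of the higher window's CPM in 1 embryo. Without the 4 libraries rich in 1 gene group (embryos 15, 41, 70 and 120) the lower calls numbered 128. Splits of the same embryos that ignored the windows gave a median of 181 calls.

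From window 5 to window 6, WHL22.150251.2 rose from a median of 80.3 to 539 CPM (mean 127 ± 149.8 SD against 681 ± 448 SD, n = 22 each), a log2 fold change of 2.43 ± 0.48 (SE, adjusted p = 3.02e-04), and 22 of 22 later embryos exceeded the earlier median. WHL22.444763.1 rose from 2.95 to 25.0 CPM (2.72 ± 0.65 SE, adjusted p = 0.00387), with 21 of 22 above. WHL22.160395.3 fell from 17.3 to 6.94 CPM (-2.04 ± 0.47 SE, adjusted p = 0.00254). WHL22.362444.0 fell from 6.83 to 1.90 CPM (-2.23 ± 0.69 SE, adjusted p = 0.0489). It passed when capped, which its naming required, and in none of the 5 other alternatives (adjusted p = 0.0572 to 0.692). There were 214 gene models higher and 140 lower, 202 and 117 of them at least 2-fold. Without the 4 libraries named above the higher calls numbered 142, and splits of the same embryos gave a median of 131 calls.

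From window 6 to window 7 the IDs named as rising had earlier medians under 5 CPM. WHL22.62613.1, picked by the rule, rose from a median of 4.40 to 57.4 CPM (mean 5.64 ± 4.36 SD, n = 22, against 329 ± 460.5 SD, n = 49), a log2 fold change of 5.85 ± 0.63 (SE, adjusted p = 6.71e-13), with 42 of 49 later embryos above the earlier median. Its spread within window 7 exceeded its mean, with a highest value of 1572 CPM. WHL22.461082.1, also picked by the rule, rose from 0.42 to 78.0 CPM (5.10 ± 0.62 SE, adjusted p = 5.38e-11). Its highest value, 1789 CPM or 17.5% of the window's CPM, was in embryo 135, a library with 19.6% spike-in counts, and with the highest embryo capped the change was 5.02 ± 0.58 (SE). WHL22.228203.1 fell from 808 to 278 CPM (mean 998 ± 498 SD against 328 ± 244 SD), a log2 fold change of -1.61 ± 0.29 (SE, adjusted p = 2.58e-05), and 22 of 22 earlier embryos were above the later median. WHL22.529855.1 fell from 16.6 to 4.08 CPM (-1.70 ± 0.35 SE, adjusted p = 2.51e-04). In this step 283 gene models were higher and 302 lower, 250 and 178 of them at least 2-fold. Higher calls made up 48.4% with TMM, 67.7% with DESeq2 size factors and 61.2% with library totals, with medians of all gene models of -0.03, 0.10 and 0.05. With number run as a covariate, 245 gene models were higher and 94 lower, of which 143 and 62 were among the 283 and 302. With runs split at every backward step of labelled time 100 were higher and 120 lower, of which 87 and 111 were among them. Run C held 34 of the 49 embryos of window 7 and lies in no other window. With number run as a covariate this contrast therefore rests on the other runs alone. With runs split at every backward step, the embryos of run C from 117 on drop out of it in the same way.

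**Figure D3:**
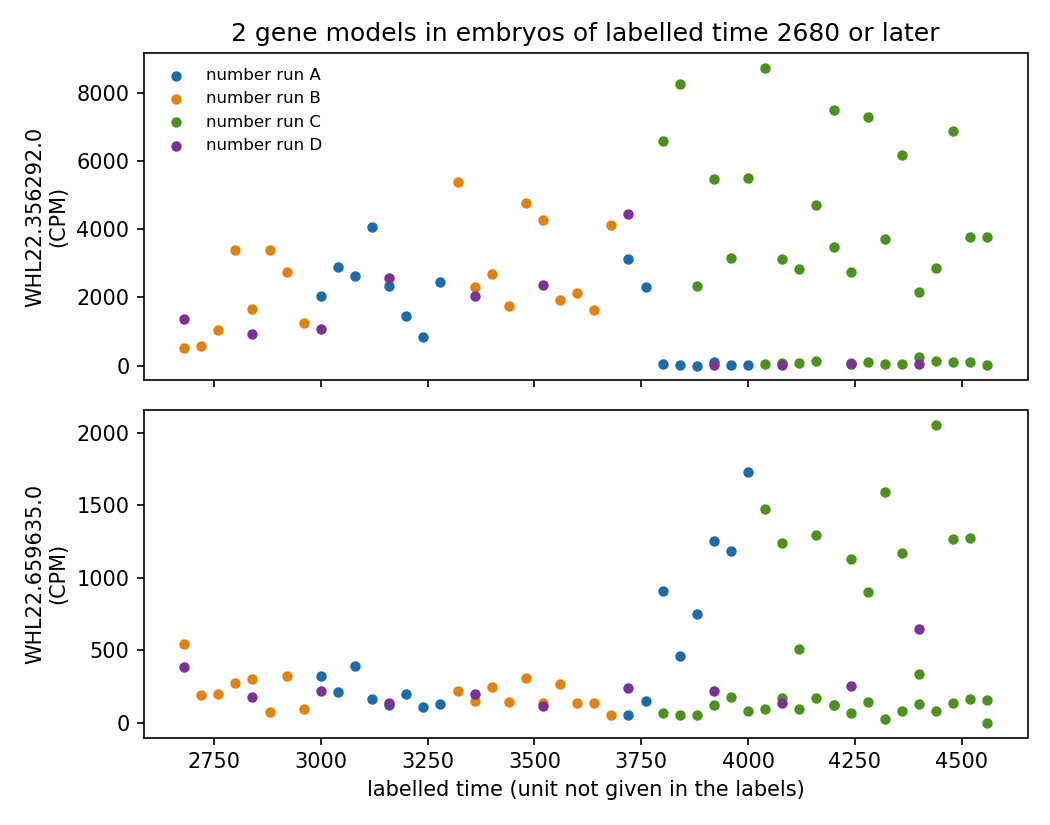
TMM-scaled CPM (y axes) of 2 gene models against labelled time (x axis, unit not given) in embryos from labelled time 2680, 1 point per embryo, coloured by number run. In run A WHL22.356292.0 lies at 850 CPM or more up to 3760 and at 113 CPM or less from 3800, and run C holds embryos at both levels.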

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

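Tests of sample outliers applied only to the comparison of runs A and C given under other observations, because every window holds over 10 embryos. In run A at labelled times 3800 to 4000, the highest of the 6 values of WHL22.356292.0 was 113.2 CPM in embryo 49, and its gap to the next took 0.731 of the range. This was 1 of 8 groups tested, and chance alone marks about 1 group in 20.

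Counts outside the gene comparisons were present in every library. Spike-in RNAs, used in no test of gene models, took a median of 6.68% of all counts and between 0.355% and 32.4%. Counts aligned outside gene models took a median of 10.7%, between 6.37% and 23.8%. Gene counts per spike-in count had medians of 4.10 in run A, 3.82 in run B, 4.23 in run C and 12.1 in run D, where they ran from 1.25 to 47.7.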

How the results depend on the processing

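Of the alternatives, the capped highest embryo, the robust test, the set without 4 libraries, the runs split at every backward step of time and the DESeq2 folds of single IDs were chosen after seeing the data. The count across windows stayed within 1.5 times in 15 of 16 settings (6552 to 9541), and 137 of 180 step counts did. The principal component's rho was 0.74 to 0.83 in its 4 alternatives. Where values moved, the cause was not tested. The set of run D alone holds 29 libraries, and the effect of that number was not tested either. Run D alone gave 3695 gene models across the windows. Its steps in order of time had 133 higher and 36 lower, 344 and 284, 146 and 91, 4 and 7, 10 and 6, and 59 and 48. Gene models highest in windows 1 to 7 numbered 1165, 419, 439, 416, 289, 442 and 525 there, and expressed genes against time did not pass (r = 0.43, permutation p = 0.0245, adjusted p = 0.196). DESeq2 size factors gave 134 higher and 47 lower in step 1, 201 lower in step 6 and 1569 highest in window 7. Library totals gave 131 higher and 34 lower in step 1, 948 and 1530 in step 2, 1148 lower in step 3, 193 lower in step 6, and 2278, 435 and 313 highest in windows 2, 4 and 5. Without a low-count filter, step 1 had 100 higher, step 4 had 313 higher and 372 lower, and step 5 had 378 higher. The DESeq2 test gave 162 higher in step 1, and 544 higher and 168 lower in step 6. Number run as a covariate gave 110 higher and 134 lower in step 1 and 94 lower in step 6. Runs split at every backward step gave 115 higher and 132 lower in step 1 and 100 higher and 120 lower in step 6. Without run D, step 1 had 118 lower and step 5 had 85 lower. A depth minimum of 33% of the median gave 49 lower in step 1 and 1466 highest in window 2. Bounds moved 120 later gave 125 higher in step 1. Capping gave 33 higher and 45 lower in step 1. Without the 4 libraries, step 4 had 128 lower and step 5 had 142 higher. The same-time correlation was 0.70 over all gene models with a count.

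Each fold change that reversed had over 88% of the higher window's CPM in 1 embryo. For WHL22.386999.0 the log2 change of 5.80 in step 1 became -0.00461 without run D, -0.14 capped and -0.0112 in DESeq2, and its -4.95 in step 2 became 0.94, 0.66 and 1.01. WHL22.19105.0 moved from -5.50 in step 1 to 2.15 without run D and 1.57 in DESeq2, and from 4.97 in step 4 to -0.11 in run D alone and -1.11 in DESeq2. WHL22.481184.0 moved from -5.37 in step 1 to 0.69 capped and 1.45 in DESeq2. WHL22.454697.0 moved from 6.37 in step 2 to -0.81 in DESeq2, and from -6.89 in step 3 to 0.17 without run D and 0.0501 in DESeq2. In run D alone WHL22.520531.0 was at -0.32 in step 3, beside 4.30, and WHL22.66561.1 at -0.0412 in step 5, beside 6.46. Of 252 fold changes of named IDs under alternatives, 191 had the same sign and stayed past the threshold, 44 had the same sign and did not, and 17 reversed. Capping is among these, though the later-named IDs had to pass it. No paired analysis of the windows was possible because the windows share no embryos or replicate numbers from the labels. Gene list tests and their alternatives were not run, since no list member could be matched. Of simulated 2-fold changes 8% were recovered in step 1 and 49% in step 6, so at this depth and number of embryos most such changes in step 1 were not detectable.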

Other observations

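The tests on the gene group, on single-embryo peaks, on same-time pairs of run C and on splits within runs were chosen after the results were seen; the others on runs A and C and on splits of the embryos were not. The values per spike-in and the IDs below were likewise chosen after they were seen. Late in the course some gene models stood at 2 levels. WHL22.356292.0 lay between 850 and 4080 CPM in the 10 embryos of run A at labelled times 3000 to 3760, and between 0 and 113 CPM in the 6 embryos at 3800 to 4000. In run D it was 1071 to 4443 CPM in 5 embryos up to 3720, and 14.0 to 37.7 CPM in 4 embryos from 3920. In run C, 21 embryos were above 1000 CPM and 13 below 300 CPM. Run C holds 14 labelled times with 2 embryos each. At 13 of them 1 embryo was above and the other below these levels, and at 1 both were above. The levels went with the title numbers: embryos 102 to 116, 122 to 125, 127 and 128 were above, and embryos 117 to 121, 126 and 129 to 135 below. Embryo 135 had 74306 gene counts and 19.6% spike-in counts, and was at 18.3 CPM or less for the 3 IDs given here. WHL22.242989.0 had the same split: it was 206 to 652 CPM in the same 10 embryos of run A and 0 to 5.8 CPM in the 6, and 250 to 552 CPM in the 5 of run D and 3.9 to 12.0 CPM in the 4. In run C it was 47.2 to 904 CPM in the 21 embryos and 0 to 40.6 CPM in the 13. WHL22.659635.0 went the other way in run A, with a median of 157 CPM up to 3760 and 1046 CPM from 3800, while in run D its medians were 199 CPM up to 3720 and 235 CPM from 3920. In run C it was 336 to 2052 CPM in 12 of the 13 embryos, 0 in embryo 135, and 28.3 to 180 CPM in the 21.

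Gene counts per spike-in count rose with labelled time within run A (r = 0.64, rho = 0.76, permutation p = 1e-05 for each, adjusted p = 4e-05 over 4 runs, n = 50, r = 0.65 without the 2 farthest times). In run B r was 0.29 and rho 0.56 (permutation p = 0.0305 and 6e-05, adjusted p = 0.0407 and 1.2e-04, n = 50, r = 0.28 without the 2 farthest). In run D both were 0.59 (permutation p = 1.5e-04 and 0.00104, adjusted p = 3e-04 and 0.00139, n = 29, r = 0.59 without the 2 farthest). The first 3 embryos of run D, 136 to 138 at times -20 to 40, had 1.25 to 2.39, embryo 139, also at 40, had 10.7, and the later ones had 8.86 to 47.7. The relation was not computed without the first 3, so a step at embryo 139 is not told apart from a gradual rise. Run C, at late times, showed no relation (r = 0.00, rho = -0.05, permutation p = 0.982 and 0.800, n = 34).

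At the 6 labelled times from 3800 to 4000 held by 1 embryo of run A and 1 of run C (embryos 102 to 107), a paired edgeR fit over 4923 gene models called 60 higher in run A and 106 higher in run C. WHL22.356292.0 was at 32.1 ± 41.4 CPM in run A and 5229 ± 2186 CPM in run C (SD, n = 6 pairs, lower in run A in 6 of 6, log2 fold change -8.05 ± 0.60 SE, edgeR adjusted p = 1.65e-06). WHL22.659635.0 was at 1046 ± 442 and 94.0 ± 49.4 CPM (3.38 ± 0.38 SE, edgeR adjusted p = 1.82e-04, higher in run A in 6 of 6). Only the real split, 1 of the 32 ways to swap runs within times, gave as many calls, and the highest other gave 0. This argues against chance, although 1 of 32 is the smallest share that the swaps can give. A fixed offset of run A as a whole is argued against: over the 166 called gene models, run A over run B at 2680 to 3600 had a median fold of 0.0734 (log2, in the direction of the call) beside 2.72 between runs A and C. The run A embryos of that test came before embryos 46 to 51, those compared with run C. An offset of that last part of run A therefore stays open. A hypothesis is that the run A embryos were further along in development than embryos 102 to 107 of the same labelled times. Over the called gene models the fold A over C went with that of window 7 over window 6 in run D, which shares no library (Pearson's r = 0.66 across gene models, which are not independent; 83.7% had the same sign), but other swaps of the runs reached an r of 0.67 in size, so this r does not set the real runs apart from them. A fixed offset of run C as a whole is argued against as well, since its same-time embryos after 4000 differed over these gene models. The median difference in log2 CPM was 1.79 in size over 14 pairs (0.06 to 2.31), beside 2.50 between embryos 102 to 107 and run A and at most 0.28 in 9 pairs of run B 40 apart. The 2.31 was the pair with embryo 135, which had 74306 gene counts, and the next highest was 2.23. An earlier-chosen test, run C after 4000 over run D in window 7, gave 0.83, between the bounds set. An offset of part of run C stays open too, and parents, rearing and wrong time labels were not tested.

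A group of 109 gene models, raised over 20 times the median (plus 1 CPM) in each of 3 libraries, took 37.6% of gene counts in embryo 70 (labelled time 1720), 32.8% in embryo 41 (3200) and 16.0% in embryo 120 (4280), against a median of 0.190% over all libraries. In these 3 libraries 63.6% to 70.2% of counts were not aligned, against a median of 55.4%, but 9 other libraries were as high as the lowest of these, up to 75.4% in embryo 145. Sequencing depth cannot be told apart, since 0 other libraries had as many counts of all kinds, although embryo 31, with the most gene counts, held 0.176%. Embryos 15 and 53 held 5.26% and 1.70% with 658494 and 1460204 counts of all kinds, so a raised share did not need great depth, and depth stays open for the 3 libraries. A stage at those times is argued against, since the highest share among 20 embryos within 80 of them was 0.701%. The next 5 libraries (embryos 15, 53, 78, 48 and 128) were ranked by the group's median log2 excess over its median CPM (plus 1 CPM), not by share. In them the group's gene models kept the proportions of embryo 70, with a lowest Spearman's rho of 0.91 across gene models, beside a median of 0.67 in 21 libraries at the median level. Embryos 153, 151 and 161 had larger shares than embryo 128 (1.69%, 1.33% and 1.15%) but median excesses of 0.38, 0 and 0, and their proportions were not compared. The proportions go with 1 source of reads in different amounts only for libraries in which the group rose as a whole, which the ranking favoured. The identity of that source was not tested, nor was a biological explanation.

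Single-embryo peaks lay almost entirely in run D. Of 54 gene models with at least 500 CPM (unscaled) and 100 counts in 1 library and at least 10 times the second library, 52 peaked in run D. Peaks occurred in 20 of 29 libraries of run D and in 2 of 134 others. These limits were set after the peaks were seen, so no p-value is given. With TMM-scaled CPM the same limits gave 47 gene models, 45 of them in run D and 45 among the 54, with peaks in 16 libraries of run D and 2 others. Embryo 145 held 23, and without it 93.5% of the others were still in run D. Shallow libraries are argued against, since 29 libraries of the other runs at or below the median depth of run D had 0.069 peaks per library beside 1.79 in run D and 1.04 there without embryo 145. Amplification of single molecules and true differences between embryos were not told apart, although 20 libraries of run D carried a peak. The gene counts alone do not separate them, and peaks among the spike-in RNAs, which could bear on this, were not looked for.

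Splits of the embryos drawn without regard to their windows test whether the calls could come from any grouping, 40 splits each with the real one included. For the test across all windows (7025, highest other 931) and for steps 2 (2453 and 606), 3 (1412 and 465), 4 (397 and 259), 5 (354 and 216) and 6 (585 and 214), only the real split, 1 of 40, reached the real count. This argues against chance but does not exclude it. A share of 1 of 40 is the smallest that 40 splits can give, and the shares were not adjusted over the tests. For step 1, 22 of 40 splits gave at least the real 131 calls, with a highest of 209, so its calls are not told apart from chance. These splits ignore the number runs. With number run as a covariate and splits within runs, 4 of 40 gave at least the real 244 calls of step 1, with a highest of 267. There too the calls of step 1 are not told apart from chance. In the same fits 1 of 40, the real one, reached the count across all windows (6552, highest other 1079) and in steps 2 (2476 and 222), 3 (1293 and 300), 4 (387 and 206), 5 (306 and 131) and 6 (339 and 242). For these the splits argue against chance but, with 1 of 40 the smallest possible share, do not exclude it. With runs split at every backward step of labelled time, and splits within those, 4 of 40 gave at least the real 247 calls of step 1 (highest 270). Only the real split, 1 of 40, reached the count across all windows (6613, highest other 850) and in steps 2 (2465 and 242), 3 (1306 and 304), 4 (387 and 197), 5 (306 and 136) and 6 (220 and 102), which argues against chance there except for step 1. The splits that ignore runs still called medians of 133, 127, 248, 181, 131 and 92 gene models in steps 1 to 6, those within runs 136, 49, 152, 130, 62 and 128, and those within backward-step runs 126, 50, 158, 138, 69 and 59, so single calls are less certain than the adjusted p states.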
